A study of Mus musculus with 6 samples.

How the data were processed

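The study measured mRNA in hearts of wild-type female mice on a high-fat diet (HFD) or normal chow (NC). Per the labels, total RNA was extracted with Trizol and libraries were made with a VAHTS mRNA-seq kit, and each diet has 3 libraries numbered 1 to 3. The deposited table holds FPKM values, which the authors computed per gene and library; the program that made them, the depth and the use of strand are not given in the sources used here. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.38, HISAT2 2.2.1, HTSeq 0.13.5, R 3.4.1, DESeq2 1.18.1 and the build mm10, without saying what each was used for. All columns of the table belong to one of the 6 libraries. Symbols came from a separate reference, matched by gene identifier, for 23718 of 23808 genes, and 90 identifiers had no symbol.

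FPKM values are not counts, and steps that 1 read would give were looked for in low values. Among genes under 0.3 FPKM, 2.40 to 4.81% of the ratios between a library and NC 1 lay within 0.02 (log2) of the commonest ratio. Steps were not found this way, but at unknown depth a small share cannot show that they are absent. No read counts were recovered and no count test was run, so no counting interval is given. An exact 0 can be a failed estimate or an absent transcript, which was not tested, and genes listed at 0, such as mitochondrial genes of HFD 1, are described by library.

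Values were transformed to log2(FPKM + 1), a pseudocount that understates changes of low genes, and genes with a mean of at least 1 FPKM over the 6 libraries were kept. Diets were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment over the 11456 tested genes, threshold 0.05), without covariates. Fold changes are HFD minus NC on that scale. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 45 lists with at least 5 tested members, and beside it with an estimated correlation and with fry. Library means of a list or a score were compared with exact two-sided permutation tests, whose smallest p with 3 against 3 libraries is 0.1. The tests were tried on simulated data first. Noise was drawn independently for each gene, and the single genes changed had a mean log2 level above 2. With 200 of 11456 genes changed, a log2 change of 1 was called in 52.5% with 5 false calls, a log2 change of 2 in 100% with 9 and a log2 change of 3 in 100% with 17. A list of extracellular matrix genes shifted by −0.4 had an adjusted p of 5.63e-16 with the preset correlation, with 0 other lists called, and of 0.0648 with the estimated one.

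The test, the 50 gene lists, the rule for named genes and most other settings were fixed before the data were examined. The rule took the 12 genes in each direction with the largest change among genes past the threshold, or, with fewer than 10 past it, the 12 in each direction with the smallest unadjusted p, leaving out predicted gene models. The second part applied, and 3 predicted models among the higher and 2 among the lower genes were skipped. A fixed panel of 13 genes was given whatever its values, as were up to 4 members with the smallest p of each list described. Of the genes the rule took, 1 is not reported here. Other settings fixed then were 2 other pseudocounts, 2 other filters, 3 scalings between libraries, eBayes without trend or robust, library weights, the replicate number as a block, each library left out, other thresholds, and other list tests. Added after seeing the data were a fit without the genes listed at 0 and fits with the mean of the atrial markers or of 5 structural RNAs as a covariate. Coordinates and overlaps come from GENCODE annotation of mm10, the build in the processing notes, matched by gene identifier, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.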

Results

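mRNA-seq libraries were made from hearts of wild-type female mice that were kept on a high-fat diet (HFD) or on normal chow (NC) between 4 and 12 weeks of age. Each diet had 3 libraries, so that 6 libraries were compared, and the values were FPKM, the fragments per kilobase of gene, scaled to the number of fragments. The table listed 23808 genes, of which 11456 had a mean of at least 1 FPKM and were tested. Read counts were not recovered from the FPKM values, so the depth of each library is unknown. The summed FPKM was 739406, 694956 and 717964 in NC 1, NC 2 and NC 3, and 576334, 687877 and 708120 in HFD 1, HFD 2 and HFD 3. HFD 1 was listed at 0 for mt-Co2, mt-Nd4, mt-Cytb, mt-Nd4l and Gm28661, whose FPKM in the other 5 libraries lay between 2516 for mt-Nd4l in HFD 3 and 43727 for Gm28661 in NC 2, and these 5 genes made up 18.0% of the summed FPKM there. Single mitochondrially encoded genes are therefore not described. The labels do not say that the libraries of a diet came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

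The comparison asked which genes differ in the heart between the diets. The 12 genes with the smallest p among those lower on HFD included Nppb, which encodes B-type natriuretic peptide, the fibrillar collagen gene Col3a1 and the immediate early genes Fos, Fosb and Ier2. Nppb was at 167 ± 22.9 FPKM on NC and 71.0 ± 6.29 FPKM on HFD (SD, n = 3 each), a log2 fold change of −1.21 (SE 0.20). Col3a1 was at 75.5 ± 19.4 FPKM on NC and 28.8 ± 9.90 FPKM on HFD (SD, n = 3 each), a log2 fold change of −1.38 (SE 0.28). Fos, a subunit of the AP-1 transcription factor, was at 48.8 ± 19.1 and 11.3 ± 7.28 FPKM (SD, n = 3 each, log2 fold change −2.13, SE 0.40). Scgb1c1, a member of the secretoglobin family of secreted proteins, was at 33.1 ± 10.8 FPKM on NC and 8.52 ± 2.95 FPKM on HFD (SD, n = 3 each, log2 fold change −1.84, SE 0.28) and had the smallest p of all genes. The other genes of this group were Spon2 (log2 fold change −1.25), the transporter gene Slc41a3 (−1.15), Fosb (−1.71), Leo1 (−1.06), which encodes a subunit of the Paf1 transcription complex, the collagen-binding proteoglycan gene Fmod (−1.50), the forkhead factor gene Foxs1 (−1.16), Ier2 (−1.10) and Chad. Chad, which encodes the cartilage matrix protein chondroadherin, was at 1.91, 2.70 and 5.91 FPKM in the NC libraries, was listed at 0 in HFD 1 and HFD 2 and was at 1.03 FPKM in HFD 3. Spon2, Fosb, Fmod and Foxs1 were also low on HFD, at means of 0.582, 0.664, 0.861 and 0.544 FPKM.

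The 12 genes with the smallest p among those higher on HFD included the transcription factor gene Zbtb16 and Fkbp5, both known targets of the glucocorticoid receptor, and the clock repressor gene Per2. Zbtb16 was at 1.16 ± 0.655 FPKM on NC and 5.11 ± 1.87 FPKM on HFD (SD, n = 3 each), a log2 fold change of 1.5 (SE 0.28). Per2 was at 3.26 ± 1.08 FPKM on NC and 9.18 ± 3.88 FPKM on HFD (SD, n = 3 each, log2 fold change 1.20, SE 0.32). Xdh, the xanthine dehydrogenase of purine breakdown, was at 11.1 ± 1.86 FPKM on NC and 25.9 ± 5.68 FPKM on HFD (SD, n = 3 each, log2 fold change 1.14, SE 0.23). The group also held Fam107a (log2 fold change 1.27), the taurine transporter gene Slc6a6 (1.08), the glutathione transferase gene Gsta3 (1.08), Fkbp5 (0.996), Btnl9 (1.03), the kinase gene Wee1 (0.91), the olfactory receptor gene Olfr1396 (0.91) and the aldehyde oxidase gene Aox1 (0.85). In all 24 of these genes the 3 HFD values lay on one side of the 3 NC values. Olfr1396 was low, at 0.421 ± 0.223 FPKM on NC and 1.67 ± 0.467 FPKM on HFD (SD, n = 3 each).

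None of these 24 genes passed the test over all genes. With limma and Benjamini-Hochberg adjustment 0 of 11456 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.281, that of Scgb1c1. At an unadjusted p of 0.05 there were 415 genes, 151 of them higher and 264 lower on HFD, where 572.8 are expected by chance. The groups did not overlap in 931 genes (8.13%, against 10% by chance), 372 with HFD above and 559 with HFD below. In simulated data of the same size 52.5% of 200 genes with a log2 change of 1, and 100% of those with a log2 change of 2, were called. Noise there was independent between genes, and the changed genes had a mean log2 level above 2. Genes of the real lists were correlated (median estimated correlation 0.342 over the lists). The simulated shares therefore cannot say how many real changes of that size would be called. Fos, at a log2 fold change of −2.13, did not pass (limma adjusted p = 0.352). With the mean of the atrial markers as a covariate only Scgb1c1 passed (limma adjusted p = 0.0458), with the mean of 5 structural RNAs as a covariate 8 genes passed, Scgb1c1 among them and all lower on HFD, and its adjusted p ranged from 0.0351 to 0.995 over the settings other than a replicate block. Leaving out NC 2 gave 1 gene, the predicted gene Gm36956 (adjusted p = 0.00224), which was named after its values were seen.

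**Figure D1:**
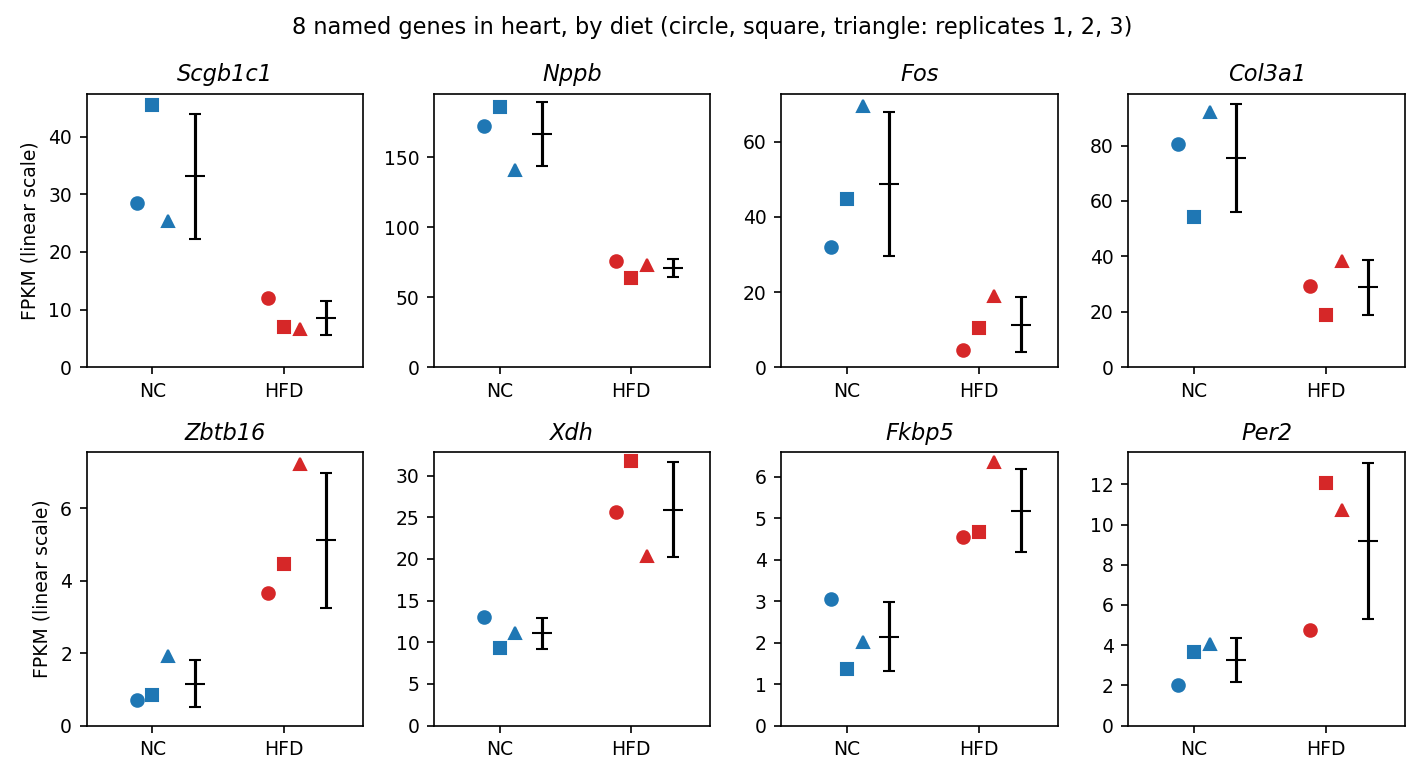
FPKM of 8 genes in each heart library (vertical axes, linear scale from 0), with NC in blue and HFD in red and circles, squares and triangles for replicates 1, 2 and 3. Black bars give the mean and SD of 3 libraries; in each panel the groups do not overlap, as for Nppb, at 141 to 186 FPKM on NC and 64.0 to 76.2 FPKM on HFD.

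By GENCODE annotation of the mm10 genome, Nppb lies on chromosome 4 from 147985788 to 147987205 on the plus strand, and its neighbour Nppa, the gene of atrial natriuretic peptide, from 148000722 to 148002079. Col3a1 lies on chromosome 1 from 45311538 to 45349706, and Fos on chromosome 12 from 85473890 to 85477273. Zbtb16 lies on chromosome 9 from 48654297 to 48836222, and Scgb1c1 on chromosome 7 from 140845547 to 140846769. All of these are protein-coding genes. Exons of Scgb1c1 overlap those of the antisense gene C330022C24Rik, exons of Nppa those of the antisense gene Gm13054, and exons of Col3a1 those of Gm47302 on the same strand. Use of strand in the counting is not given in the sources used here, so reads of these pairs may not be told apart.

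The panel of 13 genes fixed beforehand covered lipid oxidation, cardiac stress, collagen and inflammation, and none of them passed. Among the lipid genes, Pdk4, a kinase that restrains glucose oxidation, was at 27.3 ± 15.6 FPKM on NC and 40.3 ± 18.7 FPKM on HFD (SD, n = 3 each, log2 fold change 0.61, SE 0.43). The log2 fold change was 0.72 (SE 0.41) for Ucp3, 0.85 (SE 0.33) for the acyl-CoA thioesterase gene Acot1, 0.29 (SE 0.25) for Cpt1a and 0.28 (SE 0.41) for Angptl4. For Angptl4 it turned to −0.18 without NC 2 and −0.03 without HFD 2. Leaving out 1 library gave 0.117 (without NC 2) to 1.02 (without NC 3) for Pdk4, and likewise 0.197 to 1.23 for Ucp3, 0.480 to 1.17 for Acot1 and 0.0571 to 0.481 for Cpt1a. Col1a1 was at 12.7 ± 4.93 FPKM on NC and 5.79 ± 2.04 FPKM on HFD (SD, n = 3 each, log2 fold change −0.98, SE 0.31). The chemokine gene Ccl2 had a log2 fold change of −0.44 (SE 0.23). The myosin heavy chain gene Myh7 had one of −0.29 (SE 0.32), which was 0.05 without HFD 1, and Myh6 had one of −0.13 (SE 0.22), which was 0.09 after quantile normalization and 0.07 without HFD 1.

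Nppa did not separate the diets, and its spread within each diet was wide. It was at 2072, 277 and 9404 FPKM in NC 1, NC 2 and NC 3 and at 941, 227 and 4185 FPKM in HFD 1, HFD 2 and HFD 3, and its log2 fold change of −0.86 (SE 1.11) was 0.35 without NC 3 and 0.18 without HFD 2. The atrial myosin light chain gene Myl7 followed it, at 638, 36.2 and 1933 FPKM on NC and 293, 93.9 and 1292 FPKM on HFD. Of 14 atrial markers, 13 had a within-group correlation above 0.8 with the mean of the others, across libraries, and the list did not differ between the diets (camera adjusted p = 0.299). Noncoding structural RNAs also differed between libraries. Rn7s1 was at 85.6, 59.9 and 345 FPKM on NC and at 69.8, 320 and 652 FPKM on HFD.

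**Figure D2:**
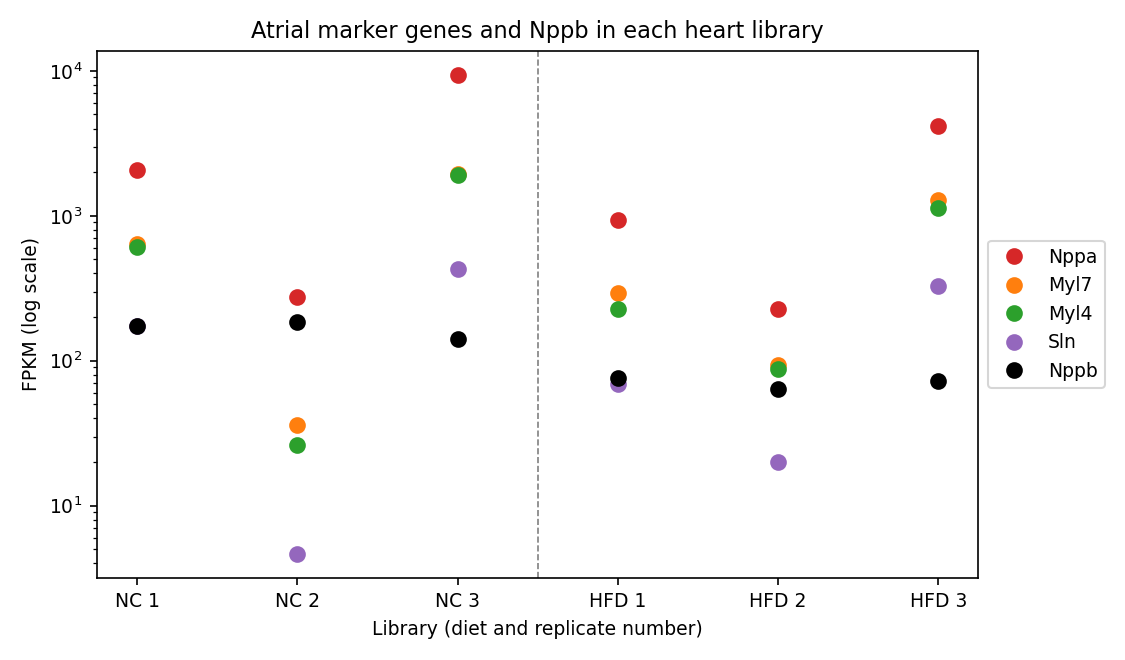
FPKM (vertical axis, log scale) of 4 atrial marker genes and of Nppb in the 6 heart libraries, with 1 point per gene and library. The atrial genes spread widely within both diets, Nppa from 277 to 9404 FPKM on NC, while Nppb lay between 141 and 186 FPKM on NC and between 64.0 and 76.2 FPKM on HFD.

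Of 50 gene lists fixed beforehand 45 had at least 5 tested members. With camera at a preset correlation of 0.01, 18 lists passed an adjusted p of 0.05, of which 8 were higher and 10 lower on HFD. None of the 18 held with an estimated correlation (smallest adjusted p = 0.515) or with fry (smallest adjusted p among them = 0.524, and 0.235 over all 45, for the skeletal muscle markers). The adjusted p with an estimated correlation therefore stands beside each list. In simulated data that test also missed a list shifted by −0.4 (camera adjusted p = 0.0648). A failure with it therefore does not show that a list is unchanged. At an unadjusted p of 0.05, 1 of the 45 lists passed with the estimated correlation and 2 with fry. The estimated correlation had a median of 0.342 over the lists, against the preset 0.01. With the preset, other splits of the 6 libraries into 3 and 3 gave a median of 15 lists. No single gene of any list passed over all genes. Library means of the diets did not overlap in 4 of the 45 lists (exact permutation p = 0.1 each, the smallest possible). These were the PPAR targets, the immediate early genes, the pericyte and smooth muscle markers and the skeletal muscle markers. Library means overlapped in all others, among them the extracellular matrix, fibroblast and clock lists (exact permutation p = 0.2 each) and the glucocorticoid list (0.3).

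Of 25 tested target genes of the PPAR nuclear receptors, 23 were higher (median log2 fold change 0.38, camera adjusted p = 3.47e-11 and adjusted p = 0.515 with an estimated correlation). The fatty acid transporter gene Cd36 was at 232 ± 78.7 FPKM on NC and 388 ± 110 FPKM on HFD (SD, n = 3 each), the acyl-CoA thioesterase gene Acot2 at 11.8 ± 0.665 and 20.1 ± 5.69 FPKM, and Fbp2 at 12.9 ± 2.60 and 21.3 ± 2.42 FPKM. Of 18 genes of fatty acid uptake and activation 14 were higher (median 0.19, camera adjusted p = 0.00443 and adjusted p = 0.567 with an estimated correlation), with 0 passing adjusted over the list alone. The call was lost without HFD 1 (adjusted p = 0.0616), although the mean log2 fold change was 0.22 there and 0.19 with all libraries, and the mean fell to 0.096 without NC 2. Of 23 genes of mitochondrial beta-oxidation 17 were higher, among them Decr1 (log2 fold change 0.55, and 0.358 without NC 3) and Cpt1b (0.54, and 0.330 without HFD 3), and 0 passed adjusted over the list alone (median 0.19, camera adjusted p = 0.00161 and adjusted p = 0.756 with an estimated correlation). The mean of 0.18 was 0.085 without NC 3 (adjusted p = 0.199), 0.19 without HFD 1 (0.0616) and 0.031 without HFD 3 (0.0573), and the call was lost in all 3. Without HFD 2 the mean was 0.311. Lists of peroxisomal lipid oxidation (adjusted p = 0.104) and of triglyceride storage and lipolysis (0.172) did not pass. Endothelial markers were higher as well (17 of 20 members, camera adjusted p = 0.00161 and adjusted p = 0.567 with an estimated correlation, lost without NC 3, HFD 1 or HFD 2). Fabp4 stands in that list and among the uptake genes. Cd36 stands among the PPAR targets and the uptake genes, and Cpt1b and Hadha among the PPAR targets and the beta-oxidation genes.

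Genes of the extracellular matrix were lower on HFD in 34 of 38 members (median log2 fold change −0.42, camera adjusted p = 1.09e-12 and adjusted p = 0.567 with an estimated correlation). Col3a1 and Fmod, 2 of the 38, passed when adjusted over the list alone. The matrix crosslinking enzyme gene Loxl1 was at 11.9 ± 2.66 FPKM on NC and 6.43 ± 0.623 FPKM on HFD (SD, n = 3 each), and Mfap4 at 29.3 ± 8.28 and 15.4 ± 4.15 FPKM. Fibroblast markers, which share several collagens with that list, were lower in 17 of 18 members (median −0.36, camera adjusted p = 1.23e-06 and adjusted p = 0.567 with an estimated correlation), and 1 passed adjusted over the list alone, Col3a1. The fibroblast transcription factor gene Tcf21 was at 18.2 ± 8.34 FPKM on NC and 9.27 ± 1.67 FPKM on HFD (SD, n = 3 each). Its log2 fold change of −0.80 ranged from −1.20 to −0.509 when 1 library was left out. Markers of valve, cartilage and Schwann cells were lower in 9 of 9 members (median −0.43, camera adjusted p = 2.47e-04 and adjusted p = 0.567 with an estimated correlation), and Chad passed adjusted over the list alone. Their mean log2 fold change went from −0.61 to −0.40 without NC 3, and that of the fibroblast markers from −0.43 to −0.66 without NC 2. The mean log2 level of the atrial markers was 5.81, 3.60 and 6.99 in NC 1, NC 2 and NC 3 and 4.62, 3.83 and 6.73 in HFD 1, HFD 2 and HFD 3.

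Immediate early genes, which respond within minutes to stimuli, were lower on HFD in 16 of 20 members (median log2 fold change −0.52, camera adjusted p = 2.82e-10 and adjusted p = 0.567 with an estimated correlation). Adjusted over the list alone 6 passed, Fos, Fosb, Ier2, Egr1, Junb and Ccn1. Egr1 was at 27.2 ± 9.47 FPKM on NC and 9.85 ± 5.95 FPKM on HFD (SD, n = 3 each). Clock genes were higher in 15 of 17 members (median 0.43, camera adjusted p = 8.77e-08 and adjusted p = 0.567 with an estimated correlation), and 2 passed adjusted over the list alone, Per2 and Per3. Per3 was at 6.11 ± 1.28 and 11.8 ± 2.86 FPKM and the repressor gene Cry1 at 1.27 ± 0.243 and 2.61 ± 0.759 FPKM (SD, n = 3 each). Genes that respond to glucocorticoids were higher in 15 of 19 members (median 0.38, camera adjusted p = 1.89e-07 and adjusted p = 0.567 with an estimated correlation), with 3 passing adjusted over the list alone, Zbtb16, Fkbp5 and Sgk1. These 3 lists passed whichever library was left out, but the mean log2 fold change shrank from −0.63 to −0.36 for the immediate early genes without HFD 1, from 0.40 to 0.27 for the clock genes without HFD 3 and from 0.39 to 0.23 for the glucocorticoid genes without NC 2. For the clock and glucocorticoid lists the library means of the diets overlapped. The glucocorticoid mean was 3.95 in HFD 1, below 4.05 in NC 1 and 3.98 in NC 3. The mean log2 level of 5 structural RNAs was 4.69, 4.52 and 6.43 in NC 1, NC 2 and NC 3 and 4.48, 6.50 and 7.65 in HFD 1, HFD 2 and HFD 3.

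Of 71 nuclear genes of oxidative phosphorylation 65 were lower (median log2 fold change −0.16, camera adjusted p = 1.45e-04 and adjusted p = 0.790 with an estimated correlation), with 0 passing adjusted over the list alone. Cox7a1 was at 1166 ± 29.9 FPKM on NC and 919 ± 186 FPKM on HFD (SD, n = 3 each). The mean log2 fold change of −0.15 fell to −0.020 after quantile normalization, where the call was lost (adjusted p = 0.614). The call was also lost with the structural RNA mean as a covariate (mean −0.12, adjusted p = 0.605), without NC 2 (−0.10, 0.597) and without HFD 3 (−0.13, 0.375). Of 16 cardiomyocyte markers 14 were lower (median −0.24, camera adjusted p = 0.00246 and adjusted p = 0.567 with an estimated correlation), with 0 passing adjusted over the list alone. The call was lost after quantile normalization (mean −0.048, adjusted p = 0.738) and without NC 2 (−0.21, 0.237), against a mean of −0.24. Leaving out 1 library gave cardiomyocyte means from −0.389 (without HFD 3) to −0.146 (without HFD 1). It gave oxidative phosphorylation means down to −0.232 (without NC 3) and sarcomere means down to −0.243 (without HFD 3). Sarcomere genes were lower in 18 of 25 members (median −0.13, camera adjusted p = 0.0382 and adjusted p = 0.871 with an estimated correlation), 0 passing adjusted over the list alone. Their mean log2 fold change of −0.13 turned to 0.03 after quantile normalization. Tnni3 and Tnnt2 are among several genes that the sarcomere list shares with the cardiomyocyte markers. Sarcomere genes passed in only 9 of 20 settings with the preset correlation, and not without NC 2 (mean −0.10, adjusted p = 0.684), HFD 1 (−0.033, 0.113) or HFD 2 (−0.11, 0.111). The troponin gene Tnni3 was at 5803 ± 198 FPKM on NC and 4296 ± 661 FPKM on HFD (SD, n = 3 each), a log2 fold change of −0.44 that turned to 0.06 after quantile normalization.

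Immune and vascular lists went both ways. Interferon-stimulated genes were higher in 33 of 38 members (median log2 fold change 0.22, camera adjusted p = 2.97e-07 and adjusted p = 0.567 with an estimated correlation). Without HFD 2 the mean fell from 0.25 to 0.047 and the call was lost (adjusted p = 0.323). The guanylate-binding protein gene Gbp4 was at 5.41 ± 0.326 and 10.9 ± 4.81 FPKM (SD, n = 3 each). Its log2 fold change of 0.82 ranged from 0.514 to 1.07 when 1 library was left out. All 6 tested genes of antigen presentation by MHC class II were lower (median −0.53, camera adjusted p = 5.10e-05 and adjusted p = 0.567 with an estimated correlation), among them H2-Eb1 at 32.9 ± 10.8 and 19.9 ± 1.84 FPKM (SD, n = 3 each). Their mean log2 fold change went from −0.53 to −0.30 without NC 1. Macrophage markers were lower in 13 of 17 members (median −0.28, camera adjusted p = 0.00126 and adjusted p = 0.567 with an estimated correlation), among them the complement gene C1qa at 59.0 ± 6.83 and 39.6 ± 9.72 FPKM (SD, n = 3 each). That call was lost without NC 1 (mean −0.14, adjusted p = 0.0516) or HFD 3 (−0.29, 0.0515), against a mean of −0.25. Endothelial markers were higher in 17 of 20 members, among them Flt1, a receptor of vascular endothelial growth factor (log2 fold change 0.67), with a median of 0.14 (camera adjusted p = 0.00161 and adjusted p = 0.567 with an estimated correlation). This call was lost without NC 3 (mean 0.11, adjusted p = 0.115), HFD 1 (0.22, 0.0616) or HFD 2 (0.094, 0.230), against a mean of 0.20. Pericyte and smooth muscle markers were lower in 15 of 16 members, among them Tagln (−0.87), with a median of −0.18 (camera adjusted p = 0.00443 and adjusted p = 0.567 with an estimated correlation), and a mean of −0.25. That call was lost with the structural RNA covariate (mean −0.27, adjusted p = 0.126) and without NC 1 (−0.15, 0.0641) or HFD 3 (−0.28, 0.0841). Ubiquitin ligase and atrophy genes were higher in 12 of 14 members (median 0.10, camera adjusted p = 0.0201 and adjusted p = 0.854 with an estimated correlation). Their mean turned to −0.03 without HFD 3 (adjusted p = 0.417). They passed in 15 of 20 settings with the preset correlation, and, against a mean of 0.15, also failed without NC 1 (mean 0.19, adjusted p = 0.0608) or NC 3 (0.13, 0.109), with the replicate block (0.15, 0.0610) and with the structural RNA covariate (0.064, 0.0786). Leaving out 1 library also raised the size of some means, to 0.386 for the interferon-stimulated genes (without HFD 3), −0.398 for the macrophage markers (without NC 2), 0.329 for the endothelial markers (without NC 1) and 0.255 for the ubiquitin ligase genes (without HFD 2). Adjusted over the list alone, 0 members of these 6 lists passed.

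**Figure D3:**
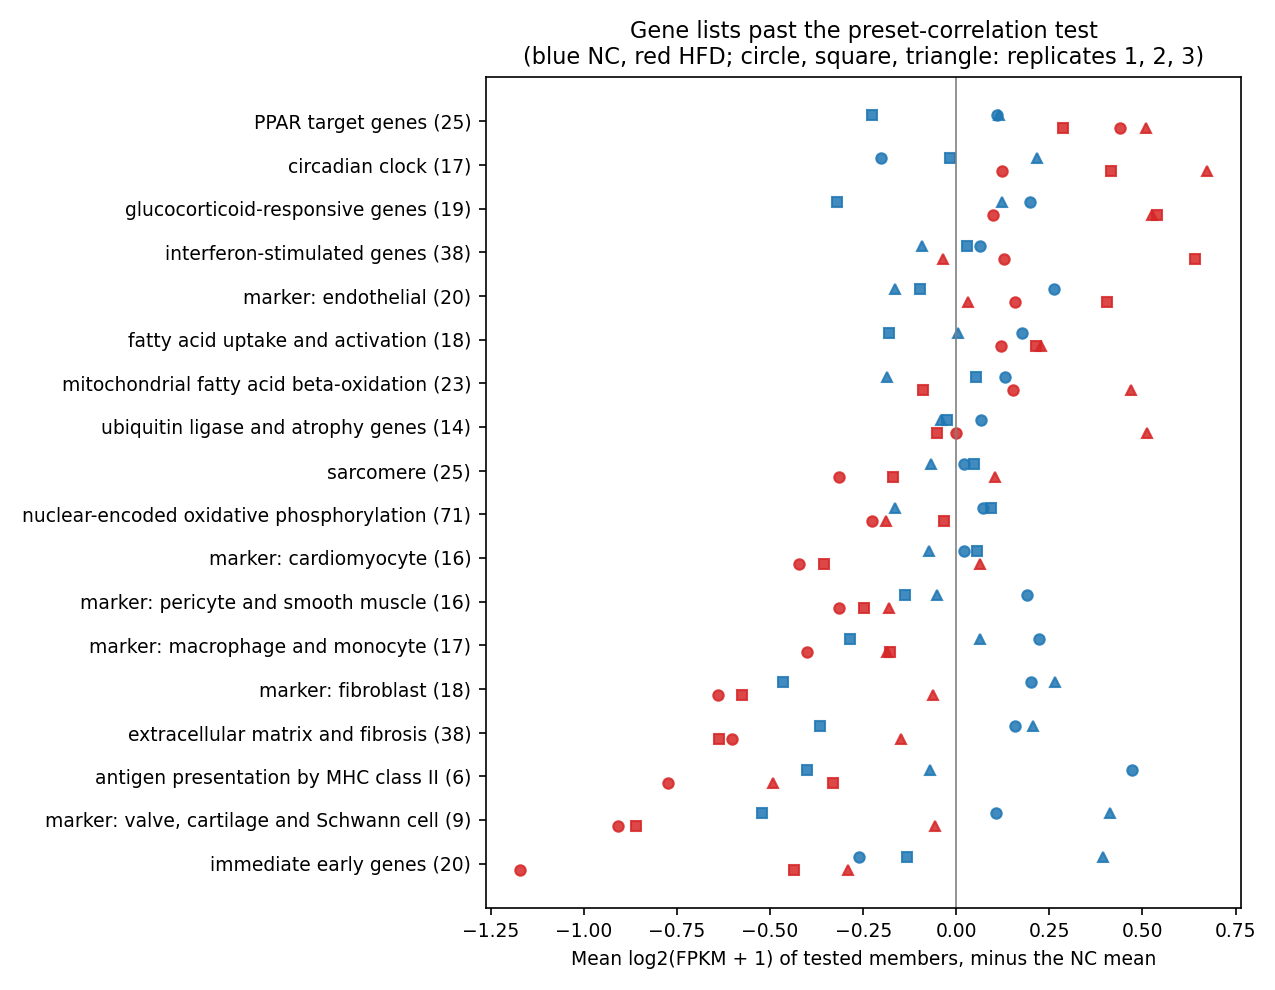
Mean log2(FPKM + 1) of the tested members of each of the 18 lists in each library, minus the NC mean (horizontal axis), with NC in blue, HFD in red, circles, squares and triangles for replicates 1, 2 and 3, and the number of members in brackets. HFD libraries lie to the right for the PPAR targets, by 0.41 on average, and to the left for the immediate early genes, by −0.63; sarcomere genes, at −0.13, turned to 0.03 after quantile normalization.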

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

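The covariate fits and the fit without genes listed at 0 were chosen after the data were seen. The number of genes past the threshold was 0 in the main fit and in 18 alternatives. It was 73 with the replicate block (22 higher, 51 lower), 8 with the structural RNA covariate (Egr1, Fosb, Scgb1c1, Fos, Pdlim4, Chad, Junb and Gpx3, named after their values were seen, all lower), 1 with the atrial covariate and 46 at an unadjusted p of 0.05 with a 2-fold change (14 higher, 32 lower). Leaving out 1 library gave 0 to 1. The labels do not say whether a replicate number marks a pair or a batch. Deviations of NC and HFD libraries of the same number correlated at 0.19, 0.086 and 0.28. Between NC and HFD libraries of different numbers the correlation ran from −0.36 (NC 3 and HFD 1) to 0.25 (NC 2 and HFD 1). Of the 6 libraries, 3 correlated best with their own number. These values do not settle whether the numbers mark a pairing or batch, which stays open. The block leaves 2 residual degrees of freedom and an infinite prior, so its count is given as it stands. The 18 lists became 0 with an estimated correlation and 0 with fry, and 15 to 23 when 1 library was left out. Quantile normalization turned the sarcomere mean to 0.028, Myh6 to 0.086 and Tnni3 to 0.061. Leaving out 1 library gave −0.177 to 0.661 for Angptl4 (below 0 without NC 2 and, at −0.029, without HFD 2), −2.19 to 0.346 for Nppa (above 0 without NC 3 and, at 0.176, without HFD 2), −0.560 to 0.047 for Myh7 and −0.266 to 0.073 for Myh6 (both above 0 without HFD 1). The cause was not tested. Of the values of single genes, 1737 kept direction and side of the threshold, 32 newly passed and 8 turned. For single lists the direction was that of the list test. Of their values 323 kept both, 70 no longer passed and 1, that of the sarcomere genes, turned. The mean of the ubiquitin ligase and atrophy genes also turned, to −0.026 without HFD 3, while the direction of their list test did not. PPAR targets, extracellular matrix, clock, immediate early, glucocorticoid and fibroblast lists passed in 20 of 20 settings with the preset correlation. No robust eBayes value exists for lists, since camera has no such option. The unknown depth limits all values.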

Other observations

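All tests on the 3 patterns below were chosen after the result was seen, whereas the counts over other splits of the libraries were planned. Several more gene lists did not pass. Among metabolic lists the camera adjusted p was 0.643 for fatty acid synthesis, 0.427 for cholesterol synthesis, 0.249 for glycolysis, 0.990 for glycogen metabolism, 0.427 for ketone and branched-chain amino acid metabolism and 0.0806 for the tricarboxylic acid cycle. Bdh1, an enzyme of ketone body use, was at 20.8 ± 11.4 FPKM on NC and 10.4 ± 3.49 FPKM on HFD (SD, n = 3 each). Its groups overlapped, and NC 2, at 33.6 FPKM, lay above NC 1 (17.2 FPKM) and NC 3 (11.6 FPKM). Cytosolic ribosomal proteins were at 0.552, inflammatory cytokines and chemokines at 0.770, endoplasmic reticulum stress at 0.427 and the fetal and hypertrophy-associated genes, which include Nppb, at 0.497. Heat shock proteins were at 0.786. Their member with the smallest p, Hspb1, was at 345 ± 20.7 FPKM on NC and 213 ± 26.3 FPKM on HFD (SD, n = 3 each). Its groups did not overlap, but it did not pass adjusted over the list alone (limma adjusted p = 0.0671). The median and the direction of the list test had opposite signs for heat shock, antioxidant (0.985), insulin (0.497), sex steroid (0.768), autophagy (0.427) and neutrophil and mast cell lists (0.811).

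Other cell types also varied within diets. Erythroid markers (adjusted p = 0.497) had a mean log2 level of 6.55, 6.89 and 5.41 in NC 1, NC 2 and NC 3 and of 6.85, 7.02 and 5.26 in HFD 1, HFD 2 and HFD 3. White adipocyte markers (adjusted p = 0.104) were at 3.16, 1.53 and 2.86 on NC and 1.31, 2.14 and 2.94 on HFD. Ucp1, the uncoupling protein of brown fat, was at 4.11 FPKM in HFD 3 and at 0.0653 FPKM in HFD 1, and was listed at 0 in the other libraries. Epicardial markers were at an adjusted p of 0.0971, skeletal muscle markers at 0.179, calcium handling at 0.811, cell cycle at 0.518, cell death at 0.299 and mitochondrially encoded genes, of which 4 were listed at 0 in HFD 1, at 0.119. Lists for T and NK cells, B and plasma cells, brown adipocytes, lung and thymus had fewer than 5 tested members. Olfr1396 (chromosome 11, 49109982 to 49114874) and Btnl9 (49165585 to 49187159) lie on the same strand of one region, and both were higher on HFD in 3 of 3 libraries.

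For the number of genes, the real split of the 6 libraries into 3 and 3 gave 0, so all 10 of the 10 splits give at least as many whatever the data, and this count cannot bear on chance. The highest other gave 84. For lists, 3 of the 10 splits, the real one included, gave at least the 18 of the real one. The other splits gave 7 to 23 lists, with a median of 15, so 18 lists is near what splits that ignore diet gave. With 10 splits a share under 0.05 cannot be had. At an unadjusted p of 0.05, 6 of the 10 splits reached the 415 genes of the real one, with up to 1275. The split that gave 84 genes put NC 2, HFD 1 and HFD 2 against the others. These libraries were the lowest in atrial markers, and also the lowest in white adipocyte markers and the highest in erythroid markers. The 3 kinds of marker therefore cannot be told apart in that split. The split of NC 1, NC 2 and HFD 1, the libraries lowest in structural RNA, gave 13. Both counts point to a structure of the samples other than diet. With an estimated correlation 0 lists passed in any split.

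The lower extracellular matrix level on HFD was the first pattern. A different share of atrial tissue was argued against, since the difference of −0.46 in the library means stayed at −0.389 (SE 0.068) with the atrial marker mean as a covariate, and so was a bias of GC content or transcript length, after whose correction it was −0.463. A lower share of fibroblasts was tried on 4 sets of genes and stays open. All 38 matrix genes differed by −0.149 relative to 9 fibroblast genes outside the list, with overlap of the groups (exact permutation p = 0.3). The spread among NC libraries was 0.10 (SD, n = 3). The 9 genes were Pdgfra, Tcf21, Pi16, Dpep1, Gsn, Clec3b, Islr, Serpinf1 and Dpt. The 33 matrix genes other than fibrillar collagens differed by −0.104 (exact permutation p = 0.5), so a lower share of fibroblasts may account for them. The 5 fibrillar collagens, a class picked after its values were seen, differed by −0.443 without overlap of the groups (exact permutation p = 0.1, the smallest possible), but by −0.160 (exact permutation p = 0.2) without Col3a1 and Col1a1, which are among the 10 smallest p of the list. The larger difference thus rests on these 2 genes and excludes nothing. An effect of diet on collagen expression and chance remain open.

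The second pattern was clock and glucocorticoid genes higher with immediate early genes lower. A different clock phase at collection is a candidate explanation for the clock genes. Per and Cry genes were higher by 0.72 while Arntl and Npas2 differed by −0.65. The means of Arntl and Npas2 lay under 1 FPKM, and they were not tested as single genes. The difference between both limbs was higher on HFD by 1.38, without overlap of the groups (exact permutation p = 0.1, the smallest possible). No immediate early gene was part of this comparison, and of the glucocorticoid genes only Per1 was. Per2, Per3 and Cry1, which have the smallest p of the clock list, are among the Per and Cry genes. The higher level of that limb is therefore partly the pattern itself. The collection time is not given in the labels. A shift in time of collection, an effect of diet on the clock and chance all remain open. Structural RNA carried into the libraries was argued against for the immediate early genes, whose difference went from −0.63 to −0.929 (SE 0.10) with it as a covariate. For the clock list (0.232, SE 0.082, from 0.40) and the glucocorticoid list (0.251, SE 0.20, from 0.39) it cannot be told apart from diet, because what remained was too uncertain, given its SE, to say how much of the uncorrected difference was kept. HFD 1 was lowest in structural RNA (4.48) and NC 3 was high (6.43), so it does not simply follow the diets.

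The third pattern was Nppb, lower on HFD in 3 of 3 libraries while atrial genes spread widely. A different share of atrial tissue was argued against: with the atrial marker mean as a covariate the log2 fold change of Nppb was −1.231 (SE 0.15), from −1.21. Nppb did not pass over all genes, so chance and an effect of diet both remain open.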
